A study of Homo sapiens with 60 samples.

How the data were processed

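RNA from A549 cells was measured in 60 libraries that form 20 groups of 3 by their labels. The groups are the vehicle, 10 µM wortmannin, and the water extracts of 6 herbal drugs at 500, 100 and 20 µg/mL, all after 24 h. The sample labels give 0.1% dimethyl sulfoxide for the vehicle, whereas the series design text gives 2%, so the vehicle concentration is uncertain. No label of a treated group gives a dimethyl sulfoxide level, so a comparison with Vehicle may also hold a solvent difference. The design text also says that lower doses were used where an extract was toxic, while every label states 500, 100 and 20 µg/mL. The labels' doses were used. All columns of the deposited table were used.

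The deposited table holds expected counts (estimated fragment counts that need not be whole), made by the authors with RSEM and not scaled for depth. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.3 and the genome build GRCh38. Per the labels, libraries were made with a strand-specific kit and sequenced as paired-end reads of 100 bases, from RNA with an integrity number above 7. The annotation release and the strand setting of the count step are not given in the sources used here, so a value of an antisense gene is uncertain. Reads that fit several genes were divided between them by RSEM, so values of paralogs, pseudogenes and gene copies are uncertain too. Of the values, 10.7% were not whole. They were rounded to whole numbers before the tests. The table lists 60675 Ensembl genes. Symbols came from the gene table of the reference for 56558 of them and from GENCODE release 29 for 497, and 3620 had none. Positions are those of GENCODE release 29 on GRCh38.

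Depth ranged from 17.7 to 30.6 M counts per library (median 24.6 M). Replicates of a group had Pearson correlations of log2 values from 0.985 to 0.993. No pair of replicates differed by so little that it could be a copy of the same library: for genes with a sum of at least 20 counts over both libraries, the chi-square per degree of freedom was 2.03 to 25.3. Normalization factors were between 0.965 and 1.05.

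Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were left out with filterByExpr over the 20 groups, which kept 17368 genes (118 of them without a symbol). Libraries were scaled with TMM. A robust quasi-likelihood model was fitted to all 60 libraries with 1 mean per group, so that every comparison shares its estimate of the spread (at most 40 residual degrees of freedom). Each of the 19 treated groups was compared with Vehicle. For each extract, a second model took its 9 libraries alone and tested the slope of log2 expression per 5-fold step of dose (20, 100 and 500 µg/mL as 0, 1 and 2), without any vehicle library. The test was edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison, and a gene was said to have changed at an adjusted p under 0.05. Log2 values of single libraries used a prior count of 2, and log2 fold changes of the model used edgeR's default. Levels are CPM (counts scaled to the same depth in each library, with TMM-scaled depth), as mean ± SD of 3 libraries. Errors of log2 values are standard errors (SE) of the model. Nothing in the sources states that the 3 replicates came from separate cultures, so p-values measure only the spread between these samples.

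The first part of the library name differs between treatments: A1 for the vehicle, 1 for wortmannin, 2 for Liriopis and Schisandrae, 3 for Longan and Zizyphi, and 4 for Polygalae and Aucklandiae. These library sets are nested in the treatments, so in a comparison with Vehicle a set difference and a treatment difference cannot be told apart. The dose slopes stay within 1 set.

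A total of 25 gene lists were fixed: NRF2 targets, AHR targets, ATF4 targets, endoplasmic reticulum chaperones, heat shock response, cholesterol synthesis, fatty acid synthesis, interferon-stimulated genes, NF-kB and cytokine genes, p53 targets, DNA replication, mitosis, FOXO targets, autophagy and lysosome, hypoxia response, metallothioneins and zinc, mesenchymal and matrix genes, MAPK early and feedback genes, lung epithelial genes, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cytosolic ribosomal proteins, replication-dependent histones (a sign of RNA quality), and markers of fibroblasts, endothelium and blood (other cell types). Each was tested with camera, with a preset correlation between genes of 0.01, adjusted over all lists and the 7 main comparisons (wortmannin and the 6 extracts at 500 µg/mL), and over all lists and the 6 dose slopes. Camera with an estimated correlation was run beside it. Of 56 calls of lists in the 7 main comparisons, 17 held with the estimated correlation.

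Named genes followed a rule. In each main comparison it takes the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol, all 3 treated libraries outside the range of Vehicle and, for extracts, a dose slope of the same sign that passed too. Where fewer than 3 genes passed, an unadjusted slope was enough. It adds up to 4 members of each called list, a panel of 20 genes, and the 3 largest rises and falls at 100 and 20 µg/mL. TXNIP, a panel gene, had 140 counts over all libraries and was not tested. The groups, tests, lists and this rule were chosen before the data were examined.

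Tests on simulated data put changes of known size into the Longan libraries. At 1.2-, 1.5- and 2-fold, 46.3, 71.6 and 83.3% of changed genes were found against Vehicle. With the same folds per 5-fold dose step, which span 2 steps from 20 to 500 µg/mL, 64.2, 80.6 and 95.5% were found in the dose slope. In these tests, 0.052 and 0.041% of unchanged genes were called. Of 200 random gene lists, 0.5% had an unadjusted camera p under 0.05. Simulated genes varied independently of each other, so this share does not give the error rate for lists of correlated genes.

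Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block, the 6 libraries of a comparison alone, slopes from all 60 libraries, and leaving out each library in turn. A fit without robust estimation, and a run without 4 libraries that stood apart (Polygalae 20 replicates 1 and 2, Liriopis 20 replicate 2 and Liriopis 500 replicate 3), were added after the data were seen. The results of some single genes are not reported here, although these genes stay in all tests, lists and counts.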

Results

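RNA was sequenced from 60 libraries of A549 cells, an established human lung adenocarcinoma line, after 24 h of treatment. The cells received the water extract of 1 of 6 herbal drugs at 20, 100 or 500 µg/mL, 10 µM wortmannin (the positive control of the series design), or the dimethyl sulfoxide vehicle (Vehicle). The drugs were Liriopis seu Ophiopogonis Tuber (Liriopis), Schisandrae Fructus (Schisandrae), Longan Arillus (Longan), Zizyphi Semen (Zizyphi), Polygalae Radix (Polygalae) and Aucklandiae Radix (Aucklandiae). Each of the 20 groups held 3 libraries. Libraries held 17.7 to 30.6 M expected counts (median 24.6 M), with group means from 21.4 M (Polygalae 500) to 27.0 M (Wortmannin), and 22750 to 24480 genes with a count. Counts from mitochondrial ribosomal RNA made up 2.44 to 3.42% of a library and those from mitochondrial messenger RNA 6.68 to 10.4%.

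The treatments differed widely in how many of the 17368 tested genes passed an adjusted p of 0.05 against Vehicle. Wortmannin changed 6499 genes (3121 rose, 3378 fell), with 214 rising and 54 falling by at least 2-fold. Among extracts at 500 µg/mL, Polygalae changed 3451 genes (1804 rose, 1647 fell), Aucklandiae 857, Zizyphi 315, Schisandrae 83, Longan 18 and Liriopis 1. In the dose slopes, which used no vehicle library, 858 genes changed with Polygalae, 168 with Aucklandiae, 61 with Zizyphi, 9 with Schisandrae, 8 with Liriopis and 6 with Longan. Of the genes that passed in Polygalae 500, 90.4% had a slope of the same sign, and 781 passed in both, although both tests share the libraries at 500 µg/mL. The counts and their order depended on the libraries in the fit. In the 6 libraries of each comparison at 500 µg/mL alone, 1722 genes passed for Aucklandiae, 914 for Zizyphi, 477 for Longan, 214 for Schisandrae and 0 for Liriopis. Slopes from all 60 libraries gave 2990 genes for Polygalae, 182 for Aucklandiae, 33 for Zizyphi, 17 for Schisandrae and 0 for Liriopis and Longan (edgeR, with 961 and 785 at an unadjusted p under 0.05 in the 9 libraries).

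**Figure D1:**
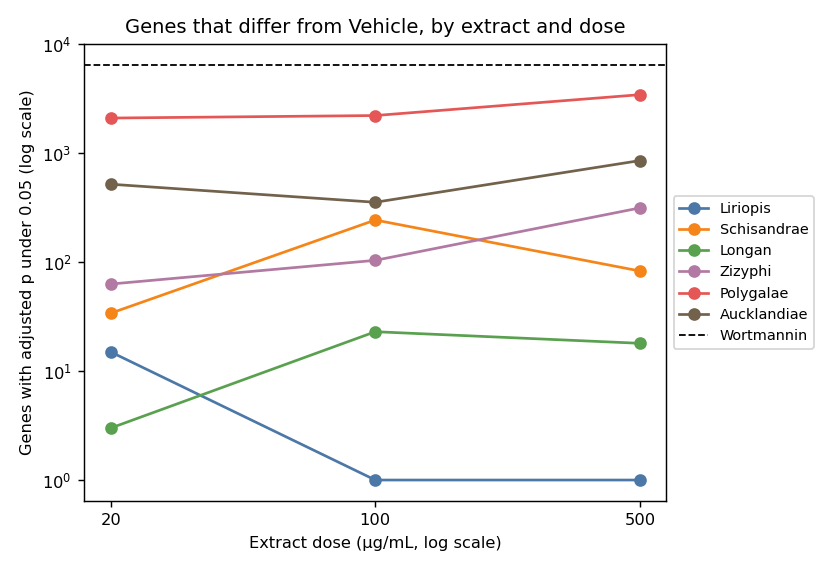
Number of genes that passed an adjusted p of 0.05 against Vehicle (vertical axis, log scale) by extract dose in µg/mL (horizontal axis, log scale), with 1 line per extract and the dashed line for Wortmannin (6499 genes). Polygalae lies highest among the extracts at 100 and 500 µg/mL, with 2221 and 3451 genes. Its 2106 genes at 20 µg/mL depended on the libraries used.

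With wortmannin, an inhibitor of phosphoinositide 3-kinases, genes of the amino acid stress response and of mitosis fell, while the growth factor gene IGF2 rose. CHAC1 (ENSG00000128965; chromosome 15, 40952962 to 40956519), which encodes an enzyme that degrades glutathione, fell from 6.46 ± 0.786 CPM (mean ± SD, n = 3) in Vehicle to 1.14 ± 0.232, a log2 fold change of −2.49 ± 0.142 (SE; adjusted p = 6.6e-22). Asparagine synthetase, ASNS (ENSG00000070669; chromosome 7, 97852118 to 97872542), went from 97.4 ± 2.35 to 30.0 ± 1.75 CPM (−1.70 ± 0.054, adjusted p = 2.2e-33). IGF2 (ENSG00000167244; chromosome 11, 2129112 to 2149603) rose from 9.16 ± 0.362 to 28.8 ± 1.43 CPM (1.65 ± 0.096, adjusted p = 2.5e-21). Other rises were those of the secreted proteoglycan gene SPOCK1 (1.26 ± 0.057), the retinol transporter gene STRA6 (1.17 ± 0.052) and the transmembrane protein gene CDCP1 (1.10 ± 0.086). Further falls were those of STC2, a secreted stress-responsive glycoprotein (−1.70 ± 0.071), the stress regulator NUPR1 (−1.39 ± 0.104) and the keratin gene KRT4 (−1.26 ± 0.055).

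Of 23 measured ATF4 targets, 21 fell with wortmannin and none rose (22 fell when adjusted over the list alone, median log2 −0.69, adjusted p = 1.03e-12 with an estimated correlation). They included PHGDH and PSAT1, enzymes of serine synthesis (−1.22 ± 0.047 and −1.18 ± 0.041), the stress transcription factor DDIT3 (−0.89 ± 0.106) and the pseudokinase gene TRIB3 (−0.69 ± 0.049). All 20 mitosis genes fell (20 adjusted over the list alone, adjusted p = 1.67e-15 with an estimated correlation). Among them were the kinesin KIF20A (−0.92 ± 0.039), the kinases PLK1 (−0.87 ± 0.036) and AURKA (−0.79 ± 0.029), and CDC20, which activates the anaphase-promoting complex (−0.86 ± 0.032). The proliferation marker MKI67 fell too (−0.48 ± 0.088). Of 24 NRF2 targets, 16 fell and 1 rose (18 and 1 adjusted over the list alone, adjusted p = 0.0149 with an estimated correlation), with heme oxygenase, HMOX1, at −0.72 ± 0.045 and the glutathione synthesis gene GCLC at −0.41 ± 0.026. Of 20 mesenchymal and matrix genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0435 with an estimated correlation), including the integrin gene ITGA2 (0.99 ± 0.059) and the gelatinase gene MMP2 (0.89 ± 0.066).

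Other lists passed with wortmannin under the preset correlation alone. Of 24 cholesterol synthesis genes, 17 rose and 1 fell (the same counts adjusted over the list alone), with MSMO1 at 0.56 ± 0.052 and SQLE at 0.27 ± 0.033 (adjusted p = 0.0624 with an estimated correlation). Among 14 NF-kB and cytokine genes, 7 rose (7 adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), and the chemokine gene CXCL8 went from 0.803 ± 0.0876 to 2.38 ± 0.370 CPM (1.56 ± 0.207). Of 12 lung epithelial genes, 5 rose (5, with 1 falling, adjusted over the list alone, adjusted p = 0.0737 with an estimated correlation), among them the surfactant lipid transporter ABCA3 (1.02 ± 0.058). MAPK early and feedback genes rose in 8 and fell in 2 of 21 cases (8 and 2 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation), with the phosphatase gene DUSP4 at 0.48 ± 0.029. Metallothionein and zinc genes rose in 3 of 5 cases (4, with 1 falling, adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), with MT2A at 0.85 ± 0.091, although reads of this gene family are hard to assign. Heat shock genes fell in 9 of 17 cases (10 adjusted over the list alone, adjusted p = 0.234 with an estimated correlation), with HSPD1 at −0.46 ± 0.038. Nuclear genes of oxidative phosphorylation fell in 13 of 24 (13 adjusted over the list alone, adjusted p = 0.462 with an estimated correlation), with ATP5F1B at −0.40 ± 0.039. Of 19 glycolysis genes, 12 fell and 3 rose (12 and 3 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation), with GAPDH at −0.36 ± 0.034.

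In the gene panel, the AHR target genes TIPARP (0.59 ± 0.046) and CYP1A1 (0.74 ± 0.197) rose with wortmannin, although the list of AHR targets did not pass. VEGFA, which encodes a vascular growth factor, fell (−0.38 ± 0.05). The insulin receptor substrate gene IRS2 rose by 0.17 ± 0.053, but without Vehicle replicate 1 its change was 0.12 and did not pass. The cell cycle inhibitor CDKN1A (0.06 ± 0.043), the cyclin CCND1 (−0.04 ± 0.034) and the quinone reductase NQO1 (−0.03 ± 0.04) did not pass. Among replication-dependent histones, a sign of RNA quality, 4 of 10 rose (4 adjusted over the list alone, camera adjusted p = 0.189). Markers of other cell types rose in 3 of 8 cases (3 adjusted over the list alone, camera adjusted p = 0.436). Wortmannin libraries form a library set of their own, so a set difference and the response cannot be told apart.

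**Figure D2:**
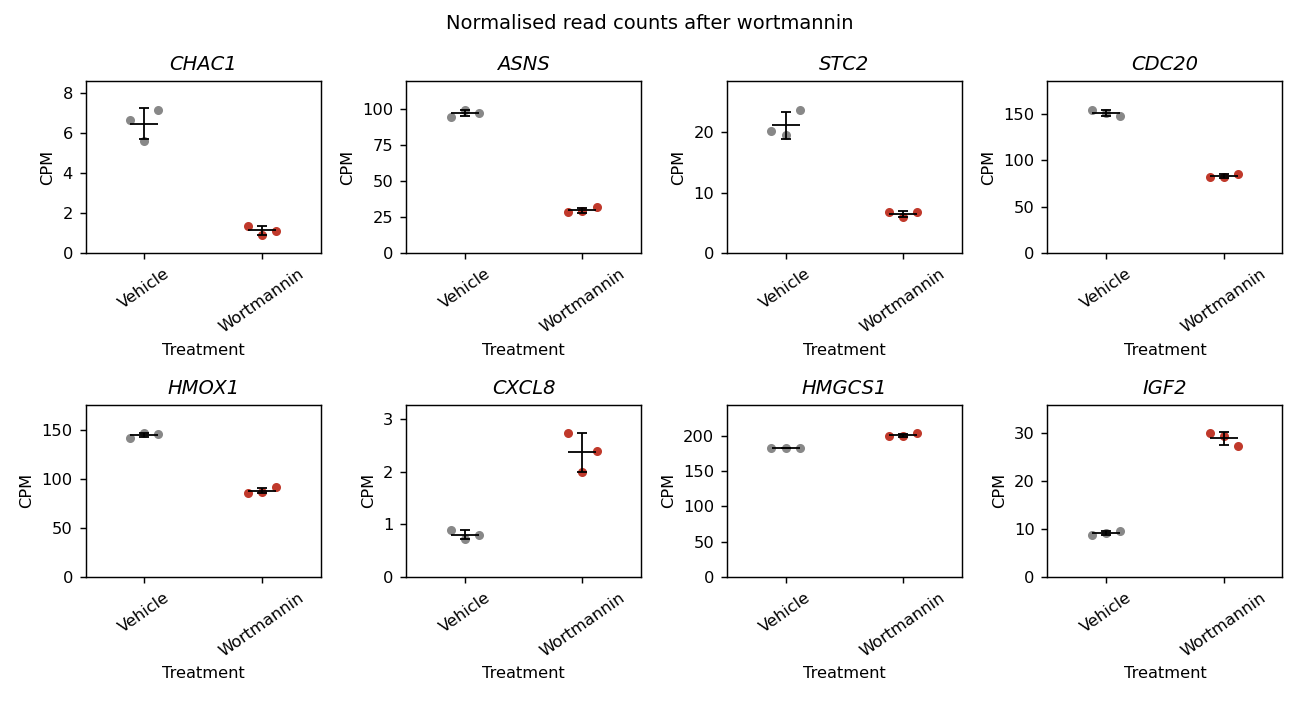
CPM of 8 genes (vertical axes) in Vehicle and Wortmannin libraries (horizontal axes), with 1 point per library (grey Vehicle, red Wortmannin) and the mean ± SD of 3 libraries in black. The 3 Wortmannin libraries lie below the 3 Vehicle libraries for CHAC1, ASNS, STC2, CDC20 and HMOX1 and above them for CXCL8, HMGCS1 and IGF2.

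With Polygalae at 500 µg/mL, genes of the lysosome and of cholesterol and fatty acid synthesis rose, while mesenchymal and matrix genes fell. The sialidase gene NEU1 (ENSG00000204386; chromosome 6, 31857659 to 31862906), whose product acts in the lysosome, rose from 14.2 ± 0.396 CPM in Vehicle to 54.6 ± 3.45 (n = 3; log2 1.94 ± 0.057, adjusted p = 2e-35), with a slope of 0.73 ± 0.056 per 5-fold dose step. UAP1L1 (ENSG00000197355; chromosome 9, 137077501 to 137084539), a relative of an enzyme that makes UDP-N-acetylglucosamine, rose from 7.21 ± 0.522 to 31.0 ± 0.762 CPM (2.11 ± 0.078, adjusted p = 1.5e-30; slope 0.87 ± 0.112). The steroid dehydrogenase gene HSD17B14 (1.71 ± 0.104), the lysosomal sialic acid exporter SLC17A5 (1.45 ± 0.088) and the glucosamine-phosphate deaminase GNPDA1 (1.37 ± 0.048) rose too. The sulfotransferase gene SULT2B1 (−1.01 ± 0.076), the imprinted neighbours H19 (−0.96 ± 0.111) and IGF2 (−0.94 ± 0.125) and the binding protein gene IGFBP5 (−0.94 ± 0.087) fell. At 100 µg/mL, NEU1 was at 39.2 ± 1.42 CPM (1.47 ± 0.058), UAP1L1 at 23.9 ± 0.261 (1.73 ± 0.078) and IGF2 at 5.25 ± 0.689 (−0.80 ± 0.119).

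All 24 cholesterol synthesis genes rose at 500 µg/mL of Polygalae (24 adjusted over the list alone, median log2 0.86, adjusted p = 9.54e-19 with an estimated correlation), and 22 rose with dose (23 adjusted over the list alone, adjusted p = 0.0214 with an estimated correlation). The sterol oxidase gene MSMO1 rose from 32.7 ± 0.236 to 82.5 ± 0.813 CPM (1.34 ± 0.051), the squalene epoxidase SQLE from 123.1 ± 2.5 to 227.7 ± 3.83 (0.89 ± 0.033), and HMGCS1, which makes the precursor of mevalonate, from 182.1 ± 0.157 to 317.8 ± 5.79 (0.80 ± 0.037). Of 14 fatty acid synthesis genes, 10 rose (11, with 1 falling, adjusted over the list alone, adjusted p = 1.18e-06 with an estimated correlation), and 7 rose with dose (10, with 1 falling, adjusted over the list alone, adjusted p = 0.0276 with an estimated correlation). Among them were the desaturases SCD (0.77 ± 0.039), FADS1 (0.65 ± 0.03) and FADS2 (0.57 ± 0.039) and the sterol sensor INSIG1 (1.01 ± 0.043).

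Of 22 autophagy and lysosome genes, 20 rose and 1 fell with Polygalae (21 and 1 adjusted over the list alone, adjusted p = 4.37e-14 with an estimated correlation). The autophagy receptor SQSTM1 rose from 775.2 ± 25.4 to 1673 ± 25.3 CPM (1.11 ± 0.032) and the folliculin gene FLCN by 1.32 ± 0.055. With dose, 14 rose (17, with 1 falling, adjusted over the list alone, adjusted p = 0.109 with an estimated correlation). Mesenchymal and matrix genes fell in 15 of 20 cases (15 adjusted over the list alone, adjusted p = 1.59e-05 with an estimated correlation), with the matrix protein THBS1 at −0.57 ± 0.041 and N-cadherin, CDH2, at −0.39 ± 0.038. With dose, 6 of them fell (14, with 1 rising, adjusted over the list alone, adjusted p = 0.0588 with an estimated correlation). Of 14 NF-kB and cytokine genes, 7 rose (8 adjusted over the list alone, adjusted p = 0.00891 with an estimated correlation), including CXCL5 (0.53 ± 0.055), CXCL2 (0.83 ± 0.157) and the inhibitor gene TNFAIP3 (0.58 ± 0.1). With dose, 2 rose (4 adjusted over the list alone, adjusted p = 0.209 with an estimated correlation). FOXO targets rose in 7 and fell in 4 of 19 cases (8 and 4 adjusted over the list alone, adjusted p = 0.0372 with an estimated correlation), with KLHL24 at 1.18 ± 0.086 and the cyclin gene CCNG2 at 0.80 ± 0.13. With dose, 3 of them rose (4 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). Mitosis genes fell in 9 of 20 cases (12, with 1 rising, adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation), including KIF20A (−0.32 ± 0.038). With dose, 1 mitosis gene fell (3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.111, and 0.292 with an estimated correlation).

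DNA replication, MAPK and lung epithelial lists passed with Polygalae under the preset correlation alone. Of 22 DNA replication genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.191 with an estimated correlation). MAPK early and feedback genes rose in 6 and fell in 4 of 21 cases (6 and 5 adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), with DUSP5 at 0.50 ± 0.036. Lung epithelial genes fell in 6 and rose in 1 of 12 (7 and 2 adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), with KRT18 at −0.33 ± 0.034. In the panel, HMOX1 (0.73 ± 0.043), TRIB3 (0.90 ± 0.046), DDIT3 (0.73 ± 0.093), TIPARP (0.33 ± 0.048) and CXCL8 (1.08 ± 0.223) rose and CCND1 fell (−0.17 ± 0.034). Among 10 replication-dependent histones, 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0527), and 3 fell with dose (4 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). Markers of other cell types rose in 1 and fell in 2 of 8 cases (the same counts adjusted over the list alone, camera adjusted p = 0.591).

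The 2106 genes of Polygalae at 20 µg/mL depended on libraries that stood apart. At this dose, 662 genes passed without replicate 1 and 3368 without replicate 3. There were 1337 and 1401 without Vehicle replicate 1 or 3. The run without the 4 outlying libraries leaves 1 library of Polygalae at 20 µg/mL, so its count cannot be set beside these. In the 6 libraries of the comparison alone 3 passed, against 1119 for Aucklandiae. The rises at 20 µg/mL of TMEM160 (1.11 ± 0.247) and the pseudogene RPL6P27 (1.09 ± 0.218) were 0.49 and 0.31 in the run without the 4 outlying libraries, which rests on 1 treated library. TMEM160 was not high in this group alone. Its mean was 6.16 CPM in Vehicle, 8.3 in Wortmannin, 11.9 in Polygalae 500 and 13 in Aucklandiae 20. The dose slope gave 489, 546 and 519 genes without replicate 1, 2 or 3 at 500 µg/mL, and 1433 and 552 without replicate 1 or 2 at 20 µg/mL, against 858.

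**Figure D3:**
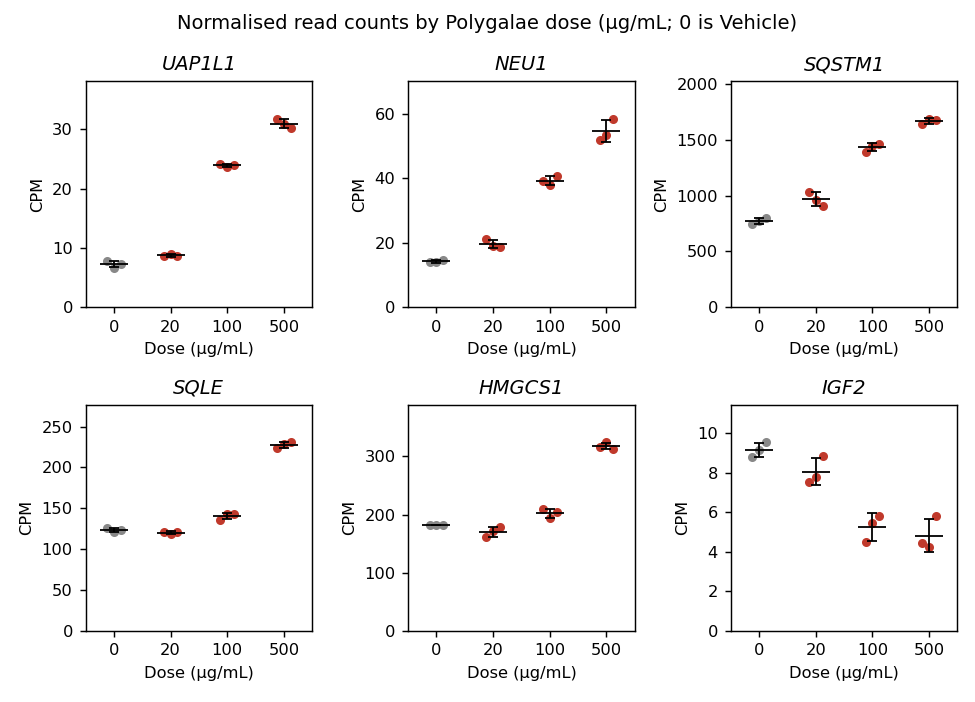
CPM of 6 genes (vertical axes) in Vehicle and in Polygalae at 20, 100 and 500 µg/mL (horizontal axes), with 1 point per library (grey Vehicle, red treated) and the mean ± SD of 3 libraries in black. At 500 µg/mL, UAP1L1, NEU1, SQSTM1, SQLE and HMGCS1 lie above Vehicle and IGF2 lies below it in all 3 libraries.

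With Aucklandiae at 500 µg/mL, C3 and GPX1 fell, HMOX1 and ANGPTL4 rose, and MAPK early and feedback genes fell slightly. The dose slope of HMOX1 with Aucklandiae did not pass, so its rise rests on the comparison with Vehicle alone. The complement gene C3 (ENSG00000125730; chromosome 19, 6677704 to 6730562) fell from 37.3 ± 0.12 to 25.1 ± 2.39 CPM (n = 3; log2 −0.58 ± 0.086, adjusted p = 9.9e-06; slope −0.28 ± 0.031). The glutathione peroxidase gene GPX1 (ENSG00000233276; chromosome 3, 49357171 to 49358600, typed in the annotation as a polymorphic pseudogene) fell from 80.6 ± 0.72 to 54.0 ± 1.39 CPM (−0.58 ± 0.072, adjusted p = 3.9e-07; slope −0.21 ± 0.021). The tetraspanin relative TM4SF4 (−0.61 ± 0.08), the lymphatic matrix gene CCBE1 (−0.64 ± 0.1) and the BMP-binding BMPER (−0.52 ± 0.101) fell too. ANGPTL4, which encodes an inhibitor of lipoprotein lipase (ENSG00000167772; chromosome 19, 8363289 to 8374373), rose from 21.1 ± 0.67 to 29.8 ± 1.1 CPM (0.50 ± 0.062, adjusted p = 8.1e-08; slope 0.13 ± 0.025), and so did TRIML2 (0.38 ± 0.056) and the laminin gene LAMA3 (0.33 ± 0.057). ANGPTL4 was also higher than Vehicle at 20 µg/mL in 3 extracts (median log2 of these 0.29), so part of its rise may not be particular to Aucklandiae.

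HMOX1 rose with Aucklandiae from 144.9 ± 2.37 to 187.8 ± 10.2 CPM (0.38 ± 0.043, adjusted p = 2e-08), and 3 of 24 NRF2 targets rose (5 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), with the glutathione synthesis gene GCLM at 0.25 ± 0.039. Of 21 MAPK early and feedback genes, 5 fell (6 adjusted over the list alone, adjusted p = 0.041 with an estimated correlation), including the phosphatases DUSP5 (−0.17 ± 0.037) and DUSP4 (−0.13 ± 0.029). With dose, 2 fell (4, with 1 rising, adjusted over the list alone, adjusted p = 0.292 with an estimated correlation). Among 5 metallothionein and zinc genes the zinc exporter SLC30A1 fell (−0.17 ± 0.034; 4 fell when adjusted over the list alone, adjusted p = 0.0379 with an estimated correlation). With dose, 1 of the 5 fell (1 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation). Of 20 mesenchymal and matrix genes, 3 fell (6, with 1 rising, adjusted over the list alone, adjusted p = 0.178 with an estimated correlation), with the actin-binding TAGLN at −0.52 ± 0.079. Lung epithelial genes fell in 2 of 12 cases (3 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation), led by the keratin KRT18 (−0.25 ± 0.034). The lysosome list had 2 rises of 22, SQSTM1 (0.20 ± 0.031) among them (2 adjusted over the list alone, adjusted p = 0.0612 with an estimated correlation). Oxidative phosphorylation had 2 of 24, NDUFV1 (0.24 ± 0.043) and CYC1 (0.21 ± 0.042) (2 adjusted over the list alone, adjusted p = 0.482 with an estimated correlation). No member of the 13 mitochondrially encoded genes passed (1 fell when adjusted over the list alone, median log2 −0.21, adjusted p = 0.411 with an estimated correlation). HMGCS1 fell by 0.18 ± 0.038.

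The count of 857 for Aucklandiae 500 moved to 544 and 421 without Vehicle replicate 1 or 2, to 457 and 519 without Aucklandiae 500 replicate 1 or 3, and to 1452 without the 4 outlying libraries. Of 168 genes in the slope, 98, 76 and 105 passed without replicate 1, 2 or 3 at 500 µg/mL. At 100 µg/mL, 355 genes passed (114 and 94 without Vehicle replicate 1 or 2, 105, 210 and 210 without Aucklandiae 100 replicate 1, 2 or 3, and 854 without the outlying libraries). At 20 µg/mL, 520 passed (241 and 101 without Vehicle replicate 1 or 2, 177 and 218 without Aucklandiae 20 replicate 2 or 3, and 1101 without the outlying libraries). The peptide deformylase gene PDF rose at 100 µg/mL from 10.3 ± 0.914 to 15.8 ± 1.65 CPM (0.61 ± 0.119).

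With Zizyphi at 500 µg/mL, ATOH8, ID4 and ID2 fell with dose and NF-kB and cytokine genes rose by small amounts. ATOH8, a helix-loop-helix transcription factor gene (ENSG00000168874; chromosome 2, 85751344 to 85788066), fell from 18.2 ± 1.87 to 10.2 ± 0.752 CPM (n = 3; log2 −0.83 ± 0.082, adjusted p = 4.7e-10; slope −0.40 ± 0.042). The inhibitors of DNA binding ID4 (ENSG00000172201; chromosome 6, 19837386 to 19840684) and ID2 (ENSG00000115738; chromosome 2, 8678845 to 8684453) fell too. ID4 went from 12.3 ± 1.27 to 7.07 ± 0.807 CPM (−0.80 ± 0.089, adjusted p = 1.3e-08) and ID2 from 117 ± 3.31 to 76.8 ± 3.71 CPM (−0.61 ± 0.06, adjusted p = 2.5e-09). ID1 and ID3, looked at after these values were seen, fell with dose as well (slopes −0.20 ± 0.023 and −0.21 ± 0.024). PDK4, which restrains pyruvate oxidation, went from 33.7 ± 0.468 to 20.4 ± 1.87 CPM (−0.73 ± 0.113) and the cyclooxygenase gene PTGS2 from 29.8 ± 1.3 to 19.1 ± 1.2 (−0.64 ± 0.127). AFAP1L2, an adaptor protein gene, rose by 0.37 ± 0.047, and the hyaluronan synthase HAS3 rose by 0.27 ± 0.05.

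Of 14 NF-kB and cytokine genes, 3 rose with Zizyphi (6 adjusted over the list alone, median log2 0.20, adjusted p = 5.92e-05 with an estimated correlation), and 3 rose with dose (5 adjusted over the list alone, adjusted p = 0.0508 with an estimated correlation). TNFAIP2 rose by 0.25 ± 0.03, BIRC3 by 0.31 ± 0.062 and NFKB2 by 0.25 ± 0.055, where the calls of BIRC3 (0.23 and 0.24) and NFKB2 (0.22 and 0.22) ended without Vehicle replicate 2 or Zizyphi 500 replicate 2. Fatty acid synthesis genes fell in 3 of 14 cases (3 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation) and with dose in 5 (8 adjusted over the list alone, adjusted p = 0.0214 with an estimated correlation), with slopes of −0.14 ± 0.015 for SCD, −0.13 ± 0.016 for the lipid regulator SREBF1 and −0.07 ± 0.015 for ACSL3. Among 10 AHR targets, 2 fell and 1 rose (the same counts adjusted over the list alone, adjusted p = 0.0493 with an estimated correlation), the aldehyde dehydrogenase ALDH3A1 at −0.41 ± 0.072 and NFE2L2, which encodes NRF2, at −0.17 ± 0.034. With dose, 1 AHR target fell (1 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). Of 20 mitosis genes only PLK1 fell (−0.18 ± 0.035; 5 fell when adjusted over the list alone, adjusted p = 0.0493 with an estimated correlation). With dose, no mitosis gene passed (0 adjusted over the list alone, adjusted p = 0.517 with an estimated correlation). CCND1 fell by 0.17 ± 0.034 at 500 µg/mL.

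Other lists passed with Zizyphi under the preset correlation alone. NRF2 targets fell in 3 of 24 cases (5, with 1 rising, adjusted over the list alone, adjusted p = 0.255 with an estimated correlation), and DNA replication genes in 1 of 22 (2 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). Heat shock genes fell in 0 of 17 (2 adjusted over the list alone, adjusted p = 0.5 with an estimated correlation). Endoplasmic reticulum chaperones rose in 2 of 18 cases (5 adjusted over the list alone, adjusted p = 0.0757 with an estimated correlation), and cholesterol synthesis genes in 1 of 24 (1 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation). Lysosome genes rose in 2 of 22 (3, with 1 falling, adjusted over the list alone, adjusted p = 0.115 with an estimated correlation). The count of 315 became 150, 128 and 178 without Vehicle replicate 1, 2 or 3, 121, 185 and 135 without Zizyphi 500 replicate 1, 2 or 3, and 630 without the 4 outlying libraries. The slope's 61 became 22 and 25 without replicate 2 or 3 at 500 µg/mL. At 100 µg/mL 104 genes passed (35 and 14 without Vehicle replicate 1 or 2, 35 and 2 without Zizyphi 100 replicate 2 or 3). At 20 µg/mL, 63 passed (10, 3 and 40 without Vehicle replicate 1, 2 or 3, 0 and 4 without Zizyphi 20 replicate 2 or 3, against 2034 at an unadjusted p under 0.05 with all libraries).

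**Figure D4:**
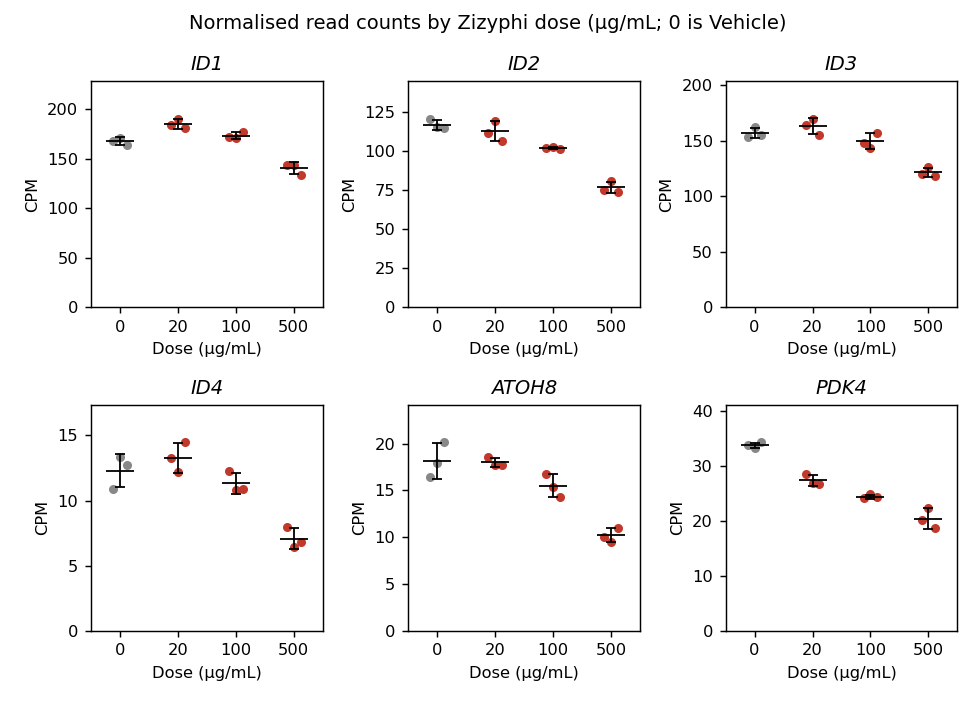
CPM of ID1 to ID4, ATOH8 and PDK4 (vertical axes) in Vehicle and in Zizyphi at 20, 100 and 500 µg/mL (horizontal axes), with 1 point per library (grey Vehicle, red treated) and the mean ± SD of 3 libraries in black. ID2 is at 117 CPM in Vehicle and 76.8 CPM at 500 µg/mL.

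With Longan at 500 µg/mL, the inhibitors of DNA binding ID2, ID3 and ID4 fell. ID2 fell from 117 ± 3.31 to 91.1 ± 6.35 CPM (n = 3; log2 −0.36 ± 0.06, adjusted p = 0.0024; slope −0.14 ± 0.021). ID4 fell from 12.3 ± 1.27 to 9.36 ± 0.47 (−0.40 ± 0.086, adjusted p = 0.027; slope −0.19 ± 0.039) and ID3 from 157 ± 4.83 to 131.6 ± 4.55 (−0.25 ± 0.056, adjusted p = 0.039; slope −0.13 ± 0.016). These 3 genes were among 18 that passed at 500 µg/mL and 6 that passed in the slope. Lists passed under the preset correlation alone, with no member passing over all genes. These were cholesterol synthesis (median log2 0.04, 0 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation), fatty acid synthesis (0.05, 1 rose adjusted over the list alone, adjusted p = 0.255 with an estimated correlation) and oxidative phosphorylation (0.06, 1 rose adjusted over the list alone, adjusted p = 0.492 with an estimated correlation). Mesenchymal and matrix genes (−0.04, 1 fell adjusted over the list alone, adjusted p = 0.157 with an estimated correlation) and mitochondrially encoded genes (−0.21, 0 adjusted over the list alone, adjusted p = 0.331 with an estimated correlation) were the 2 lists with a negative median. The calls of ID3 ended in each of the 6 omissions of 1 library (−0.28 to −0.23) and those of ID4 in 5 (−0.43 to −0.34, all but Vehicle replicate 1). That of ID2 ended without Longan 500 replicate 3 (−0.31). The 18 genes became 9, 4 and 6 without Vehicle replicate 1, 2 or 3, 3, 9 and 4 without Longan 500 replicate 1, 2 or 3, 50 with DESeq2 and 140 without the outlying libraries. In the 6 libraries of the comparison alone, 477 passed. The slope gave 1 without Longan 20 replicate 1.

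With Schisandrae at 500 µg/mL, SELENOW, DIO2 and GPX1 fell and HMOX1 rose. The dose slope of HMOX1 did not pass, so its rise rests on the comparison with Vehicle alone. SELENOW (ENSG00000178980; chromosome 19, 47778572 to 47784686), a small selenoprotein gene, fell from 54.4 ± 2.86 to 42.9 ± 0.928 CPM (n = 3; log2 −0.34 ± 0.061, adjusted p = 0.0019; slope −0.14 ± 0.023). The deiodinase gene DIO2, also a selenoprotein gene, fell from 89.4 ± 1.23 to 74.5 ± 0.634 CPM (−0.26 ± 0.039, adjusted p = 0.0001; slope −0.13 ± 0.023). GPX1 fell from 80.6 ± 0.72 to 64.2 ± 3.33 (−0.33 ± 0.071, adjusted p = 0.019; slope −0.19 ± 0.026). HMOX1 rose from 144.9 ± 2.37 to 179 ± 7.6 CPM (0.30 ± 0.043, adjusted p = 5.2e-05) and CYP1B1, an AHR target, from 99.9 ± 2.29 to 113.5 ± 3.15 (0.18 ± 0.045, adjusted p = 0.04; slope 0.15 ± 0.025). They were the single risers of 24 NRF2 targets (3 adjusted over the list alone, adjusted p = 0.0948 with an estimated correlation) and of 10 AHR targets (2 adjusted over the list alone, adjusted p = 0.0704 with an estimated correlation).

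Further lists passed with Schisandrae under the preset correlation alone, with 0 members passing over all genes. These were heat shock genes (3 rose adjusted over the list alone, adjusted p = 0.44 with an estimated correlation), cholesterol synthesis (3 fell adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), fatty acid synthesis (1 fell adjusted over the list alone, adjusted p = 0.282 with an estimated correlation) and mesenchymal genes (1 rose and 2 fell adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). The call of CYP1B1 ended in each of the 6 omissions of 1 library (0.16 to 0.20) and that of GPX1 in 5 (−0.33 to −0.29; all but Schisandrae 500 replicate 1). The count of 83 became 18, 25 and 29 without Vehicle replicate 1, 2 or 3, 29, 19 and 18 without Schisandrae 500 replicate 1, 2 or 3, and 207 without the outlying libraries. The slope's 9 genes became 1, 0 and 0 without replicate 1, 2 or 3 at 500 µg/mL, 5 and 2 without replicate 1 or 2 at 20 µg/mL and 21 without replicate 3 at 100 µg/mL. With all 9 libraries there were 1176 at an unadjusted p under 0.05 and 19 with DESeq2. At 100 µg/mL 244 genes passed (8, 93 and 44 without Vehicle replicate 1, 2 or 3, 113, 605 and 0 without Schisandrae 100 replicate 1, 2 or 3). At 20 µg/mL, 34 passed (0, 2 and 5, and 73, 0 and 0, in the same order).

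With Liriopis at 500 µg/mL, 1 gene passed. The fibrinogen chain gene FGA (ENSG00000171560; chromosome 4, 154583126 to 154590766) fell from 194.8 ± 4.41 to 173.7 ± 8.44 CPM (n = 3; log2 −0.16 ± 0.031, adjusted p = 0.043), with 1431 genes at an unadjusted p under 0.05 and 6 genes by DESeq2. The median of 14 NF-kB and cytokine genes was 0.11 (0 passed over all genes and 0 adjusted over the list alone, adjusted p = 0.00388 with an estimated correlation), with CXCL8 at 0.56 ± 0.233 (adjusted p = 0.56). In the slope the list did not pass (camera adjusted p = 0.0528, and 0.439 with an estimated correlation). Lists that passed under the preset correlation alone, with 0 members passing over all genes, were cytosolic ribosomal proteins (0 of 28 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation) and oxidative phosphorylation (2 rose adjusted over the list alone, adjusted p = 0.363 with an estimated correlation). Others were heat shock genes (0 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation) and fatty acid synthesis (0 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation). At 100 µg/mL the transcription factor gene ETV6 fell (−0.28 ± 0.053, adjusted p = 0.033), and at 20 µg/mL the early response gene IER2 rose (0.22 ± 0.041, adjusted p = 0.018), as 1 of 15 genes. Of the 15, 10 rose by at least 2-fold, unlike IER2, and the count ranged from 0 to 39 when each library was left out in turn. The call of ETV6 ended in 5 of 6 omissions of 1 library (−0.30 to −0.26; all but Vehicle replicate 1) and that of IER2 without Vehicle replicate 1 or 3 or Liriopis 20 replicate 2 or 3 (0.19 to 0.22). That of FGA ended without Vehicle replicate 1 (−0.15) or 3 (−0.17) or Liriopis 500 replicate 3 (−0.13). Without the 4 outlying libraries, which include that replicate, 172 genes passed at 500 µg/mL. The slope's 8 genes, most of them pseudogenes or genes with few counts, became 2 and 3 without Liriopis 500 replicate 1 or 2 and 21 without replicate 3.

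Interferon-stimulated genes, p53 targets and hypoxia genes passed as lists in none of the 7 main comparisons. With wortmannin, 5 of 18 interferon-stimulated genes rose (5 adjusted over the list alone, camera adjusted p = 0.0849), 4 of 21 p53 targets rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.662). Of 20 hypoxia genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.222). With Polygalae the counts were 3 rising and 1 falling, 4 rising and 8 falling, and 3 rising and 6 falling (camera adjusted p = 0.662, 0.976 and 0.649).

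**Figure D5:**
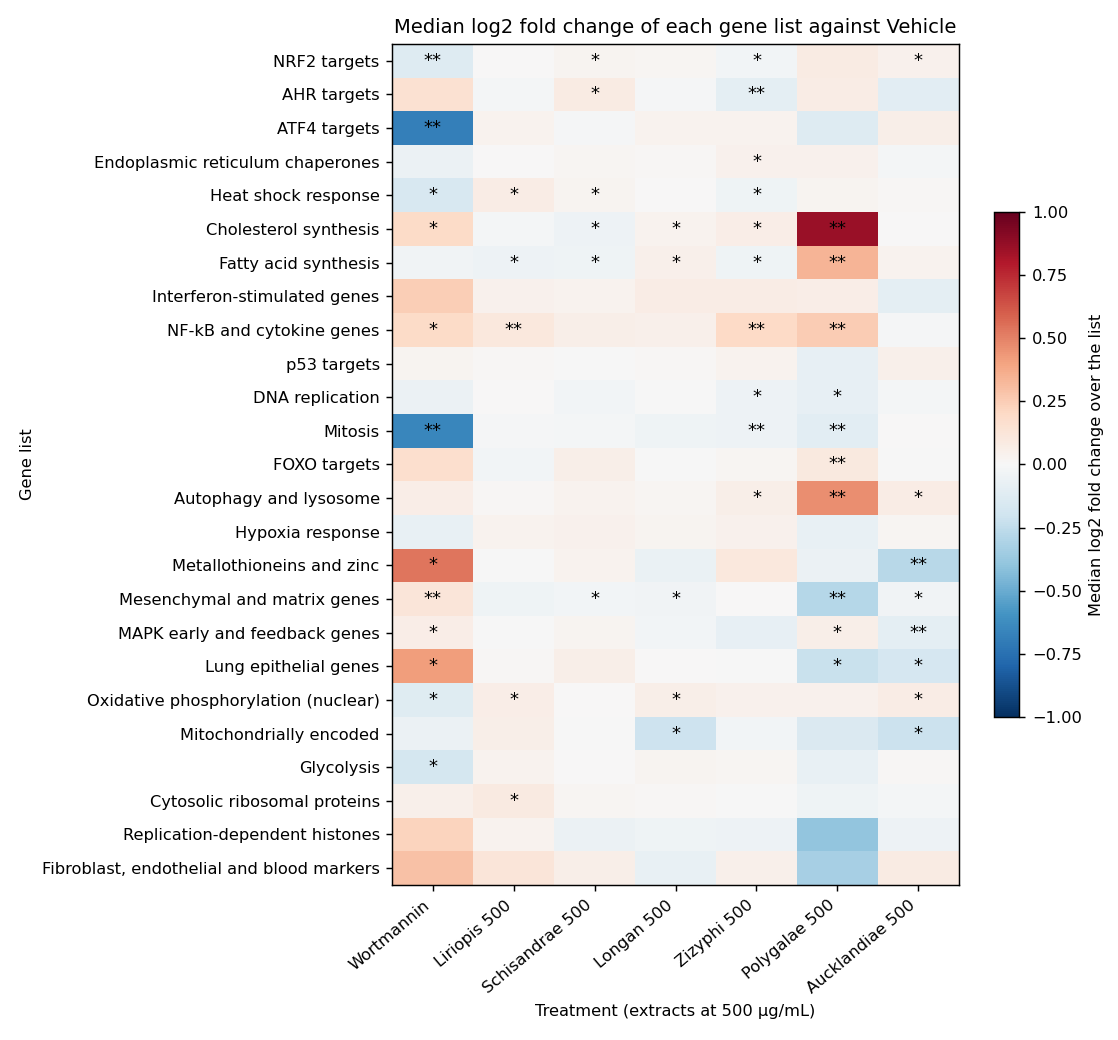
Median log2 fold change against Vehicle (colour) of the 25 gene lists (vertical axis) in the 7 main comparisons (horizontal axis). A star marks a camera adjusted p under 0.05 with the preset correlation, and 2 stars one that also passed with an estimated correlation. In all, 17 of 56 calls have 2 stars.

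Direct contrasts between extracts at 500 µg/mL asked where responses differed. TRIB3 was higher with Polygalae (111.9 ± 2.95 CPM, n = 3) than with Zizyphi by 0.75 ± 0.045 (adjusted p = 1.3e-20) and than with Aucklandiae by 0.82 ± 0.046 (adjusted p = 2.6e-22). Polygalae and Aucklandiae share a library set, while Zizyphi belongs to another, so there a set difference cannot be told apart from the treatments. HMGCS1 was higher with Polygalae than with Aucklandiae by 0.98 ± 0.038. CXCL8 was higher with Polygalae than with Aucklandiae by 1.52 ± 0.236, while Zizyphi and Polygalae differed by −0.55 ± 0.212 for this gene, which did not pass (adjusted p = 0.066). Across genes, the dose slopes of Schisandrae and the change with wortmannin had a Spearman rho of 0.175 ± 0.046 (jackknife SD over libraries), those of Zizyphi 0.116 ± 0.031, Polygalae 0.0122 ± 0.062, Longan 0.0112 ± 0.037, Aucklandiae −0.00979 ± 0.037 and Liriopis −0.0648 ± 0.08. Over genes with a mean of at least 5 CPM these were, in the same order, 0.306, 0.188, 0.0792, 0.0292, −0.0601 and −0.154. Genes are not independent replicates, so no p-value is given. Of genes in the Polygalae slope, 174 rose and 106 fell with both treatments, where independent lists would share 91.1 and 68.3. There were 125 that fell with Polygalae and rose with wortmannin, and 108 that rose with Polygalae and fell with wortmannin, where 63.1 and 98.6 would be shared. These expected numbers take every gene as equally likely to pass, whatever its level. Like and opposite directions both exceeded them, so the excess is no measure of a shared response. Of genes in the Aucklandiae slope, 68 fell with the extract and rose with wortmannin, where independent lists would share 23.4. Another 13 rose and 26 fell with both (6.83 and 25.3 would be shared), and 8 rose with Aucklandiae and fell with wortmannin (7.39 would be shared). ID2, ID3 and ID4 fell with dose of both Longan and Zizyphi, which belong to the same library set, where independent lists would share 0.00875 genes.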

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

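The tests of library sets as a source of the 20 µg/mL pattern and of the Polygalae pattern were chosen only after the results were seen. The others of this part were planned.

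Genes whose dose slope passed in both of 2 extracts with opposite signs are given with the difference of the slopes (log2 per 5-fold dose step ± SE). This happened in 6 genes for Zizyphi and Polygalae, 3 for Zizyphi and Aucklandiae and 18 for Polygalae and Aucklandiae, and in 0 genes for the other 12 pairs. The difference passed for each of these genes in a test over all genes (671, 88 and 674 genes passed in all), but choosing genes by opposite slopes that passed all but fixes this, so that it adds no evidence.

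Between Polygalae and Zizyphi, the fatty acid desaturase SCD rose with Polygalae (0.38 ± 0.032) and fell with Zizyphi (−0.14 ± 0.015), a difference of 0.52 ± 0.034. The same direction held for PHLDA1, a MAPK-responsive gene (0.19 ± 0.033). The keratin KRT4 (−0.55 ± 0.039), the adaptor AFAP1L2 (−0.28 ± 0.035) and the hyaluronan synthase HAS3 (−0.26 ± 0.043) fell with Polygalae and rose with Zizyphi. Aucklandiae minus Zizyphi gave −0.14 ± 0.022 for the chaperone CALR, which fell with Aucklandiae and rose with Zizyphi.

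Aucklandiae minus Polygalae, within 1 library set, gave −0.53 ± 0.045 for HMGCS1, −0.48 ± 0.046 for the chemokine gene CXCL5, −0.47 ± 0.072 for the membrane protein gene CDCP1, −0.37 ± 0.038 for the desaturase FADS2 and −0.28 ± 0.029 for the phosphatase DUSP4. All 5 rose with Polygalae and fell with Aucklandiae. ANGPTL4 went the other way (0.48 ± 0.062), falling with Polygalae (−0.35 ± 0.057) and rising with Aucklandiae (0.13 ± 0.025).

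Cholesterol synthesis and lysosome genes rose with the dose of Polygalae: 36 of 46 measured members passed in the slope, with a median of 0.31. In the slope, the cholesterol list passed with an estimated correlation (adjusted p = 0.0214) and the lysosome list did not (adjusted p = 0.109 with an estimated correlation). Without the 2 libraries at 20 µg/mL that stood apart, 28 of the 36 still passed in the 7 libraries left, with a median slope of 0.34, which argues against these libraries as the source. A difference between library sets is argued against by Aucklandiae of the same set, where the median log2 fold change of the members at 500 µg/mL was 0.06, against 0.66 with Polygalae. Of 100 splits of the 9 libraries, only the real one gave as many genes in the slope (858, against 152 in the highest other split). These splits counted all genes rather than the 46 members, and take the 9 libraries as exchangeable. They therefore cannot exclude chance for this pattern. A response to the extract stays as a hypothesis, found and tested on the same libraries.

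Processed pseudogenes were high in Polygalae 20 replicate 2 and Liriopis 20 replicate 2, where 161 and 95 of 509 tested ones exceeded the mean of their 2 sister replicates by more than 1 on the log2 scale. They made up 0.2767 and 0.2737% of the counts of these libraries, against a median of 0.1738% over all libraries. Reads from genomic DNA are argued against by 376 olfactory receptor genes, silent in these cells: 0 of the 2 libraries lay above the other 58 in their share (0.896 and 1.43 CPM, against 0.809 to 2.37). Reads shared with abundant parent genes may be the source, since the rise was larger where the parent was in the upper tertile of levels than in the lower tertile, by at least 0.37 in both libraries (medians of 1.04 against 0.35, and of 0.53 against 0.16; two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, and 5e-05). The permutations shuffled pseudogenes within a library and treat them as independent, so these p-values do not measure the spread between libraries. No biological explanation was tested, since replicates of a group do not differ by design.

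At 20 µg/mL, 52 genes differed from Vehicle in the same direction in 3 or more extracts (30 higher, 22 lower), and 45 of them had no dose trend in any extract. All 6 comparisons share the 3 Vehicle libraries, which favours agreement in direction, and the number that unchanged genes would give was not computed. The count also draws on the 2106 genes of Polygalae at 20 µg/mL, which became 662 without Polygalae 20 replicate 1. IER2 was higher in 5 extracts, and PABPC1 was lower in 4. A difference between library sets could produce this, and the test leaves it open. It took all genes and all 3 doses, centred on the mean of the 6 extracts, where unrelated profiles have an r near −0.2. The mean r was −0.122 for pairs of the same set and −0.216 for other pairs, but Polygalae and Aucklandiae of 1 set had −0.214 and Longan and Aucklandiae of different sets −0.113. The exact one-sided p was 0.0667, and 15 pairings of 6 extracts allow none lower. Levels particular to the vehicle libraries would shift Wortmannin alike too, which held for 48.1% of the 52 genes (25; exact 95% interval 34 to 62.4). The interval treats genes of the same libraries as independent. Wortmannin itself changed 6499 genes, so the share cannot decide, and this explanation stays open as well. A response to all extracts at the lowest dose, or a solvent difference from Vehicle, cannot be told apart from these.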

How the results depend on the processing

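The fit without robust estimation and the run without the 4 libraries that stood apart were chosen only after the results were seen. The other alternatives were planned.

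Among 25 counts of changed genes (19 against Vehicle, 6 dose slopes), RLE scaling left all 25 within 1.5 times the reported count, DESeq2 and the replicate block 17 each, and no filter on low counts 7. No named result reversed among the 258 that passed: 253 kept their call with DESeq2, 249 without the filter, 256 without robust estimation, 257 with the block, 257 with RLE, 252 without the 4 libraries and 242 in the 6 libraries alone. When each library was left out in turn, 1229 of 1548 refits kept the call. All 56 calls of gene lists held under RLE scaling, no filter, the block and centring on the median of all genes, and 17 held with an estimated correlation. Groups of 3 libraries limit small changes: 46.3% of simulated 1.2-fold changes in the Longan libraries were found against Vehicle. Restricting the similarity of treatments to genes with a mean of at least 5 CPM moved 11 of 21 pairs by more than 1 jackknife SD, for example Schisandrae and Wortmannin to a rho of 0.306 and Zizyphi and Wortmannin to 0.188. For each value that follows the cause was not tested, unless fewer libraries or more genes tested are part of the alternative.

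With DESeq2, the counts at 500, 100 and 20 µg/mL were 6, 4 and 30 for Liriopis and 50, 50 and 34 for Longan, and 13 and 19 in the slopes of Liriopis and Schisandrae. Without the filter, which tests more genes, they were 185, 225 and 282 for Liriopis, 186, 882 and 261 for Schisandrae and 263, 347 and 266 for Longan. At 100 and 20 µg/mL there were 401 and 315 for Zizyphi and 698 and 845 for Aucklandiae. The slopes gave 132 for Liriopis, 61 for Schisandrae, 41 for Longan, 145 for Zizyphi and 298 for Aucklandiae. The fit without robust estimation gave slope counts of 3 for Liriopis, 4 for Schisandrae, 2 for Longan and 40 for Zizyphi. Slopes taken from all 60 libraries, as the difference between 500 and 20 µg/mL, gave 0 for Liriopis (961 with an unadjusted p under 0.05 in the reported fit), 17 for Schisandrae, 0 for Longan (785 in the same way), 33 for Zizyphi and 2990 for Polygalae.

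With the replicate number as a block, the counts at 500 and 100 µg/mL were 3 and 2 for Liriopis and 34 and 39 for Longan. The slopes gave 13 for Liriopis, 14 for Schisandrae, 13 for Longan and 96 for Zizyphi. No source used here states that equal numbers mark a shared day: residuals of libraries with the same number correlated with a mean r of 0.00187 over 570 pairs (−0.113 to 0.183), against −0.000929 for 1140 pairs of other numbers, and 25 of 60 libraries correlated best with their own number.

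In the 6 libraries of each comparison alone, the counts at 500, 100 and 20 µg/mL were 0, 21 and 58 for Liriopis, 477, 518 and 502 for Longan, 914, 457 and 312 for Zizyphi and 1722, 928 and 1119 for Aucklandiae. Schisandrae had 214 at 500 and 288 at 20 µg/mL, and Polygalae 3 at 20 µg/mL. Without the 4 libraries, the counts at 500, 100 and 20 µg/mL were 207, 1192 and 186 for Schisandrae, 140, 195 and 83 for Longan, 630, 317 and 310 for Zizyphi and 1452, 854 and 1101 for Aucklandiae. Liriopis had 172 and 77 at 500 and 100 µg/mL, with 106 for Polygalae at 20 µg/mL.

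Leaving out each library of a comparison in turn gave 5613 to 5781 genes for Wortmannin. At 500, 100 and 20 µg/mL the ranges were 0 to 3, 0 to 1 and 0 to 39 for Liriopis, and 18 to 29, 0 to 605 and 0 to 73 for Schisandrae. In the same order they were 3 to 9, 1 to 17 and 0 to 2 for Longan and 121 to 185, 2 to 72 and 0 to 56 for Zizyphi. Polygalae gave 2713 to 2907, 1581 to 1837 and 662 to 3368, and Aucklandiae 421 to 669, 94 to 256 and 101 to 368. In the slopes they were 2 to 21 for Liriopis, 0 to 21 for Schisandrae, 1 to 9 for Longan, 22 to 75 for Zizyphi, 489 to 1433 for Polygalae and 76 to 193 for Aucklandiae. The count moved by over 1.5 times in 100 of 168 omissions.

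Comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. In the fit of 6 libraries, the real split and the highest other gave 7498 and 0 genes for Wortmannin. At 500, 100 and 20 µg/mL they gave 0 and 2, 21 and 4, and 58 and 12 for Liriopis, 214 and 7, 327 and 2, and 288 and 5 for Schisandrae. Longan gave 477 and 1, 518 and 3, and 502 and 2, and Zizyphi 914 and 1, 457 and 2, and 312 and 3. Polygalae gave 4050 and 1, 2878 and 1, and 3 and 0, and Aucklandiae 1722 and 2, 928 and 3, and 1119 and 2. For slopes, 100 splits of 9 libraries were drawn. As many genes as the real split came from the real split alone for Zizyphi (61, highest other 24), Polygalae (858, 152) and Aucklandiae (168, 27). As many came from 2 splits for Schisandrae (9, 82) and from 3 for Liriopis (8, 80) and Longan (6, 6). For the first 3 extracts the share was under 0.05, which takes the 9 libraries as exchangeable. No source used here states that libraries of 1 dose were separate cultures, so a chance difference between dose groups is not excluded. For the other 3 the share in 100 draws was under 0.05 but close to it. Other splits with several times the real count point to a structure among the libraries of Liriopis and Schisandrae that a slope over dose does not describe. The split of Schisandrae with 82 genes put its 3 libraries at 100 µg/mL together at 1 end, a grouping by dose without a steady trend. What the structure of Liriopis is was not tested.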

Other observations

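The selenoprotein and lysosome class tests of this part were chosen only after the results were seen, and the genes of the opening paragraphs were picked after their values were seen. The BMP tests were written before theirs.

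With Polygalae at 500 µg/mL, ATF4 targets went both ways, so that the list did not pass (6 of 23 rose and 11 fell; 8 and 12 adjusted over the list alone; camera adjusted p = 0.0946). Members that rose included TRIB3 (0.90 ± 0.046), DDIT3 (0.73 ± 0.093), NUPR1 (0.50 ± 0.088) and the transcription factor CEBPB (0.48 ± 0.132). Members that fell included ASNS (−0.48 ± 0.051), PHGDH (−0.46 ± 0.046), PSAT1 (−0.33 ± 0.04) and the mitochondrial folate enzyme ALDH1L2 (−0.62 ± 0.065), along with SESN2, a brake on mTORC1 (−0.69 ± 0.069), and CHAC1 (−0.92 ± 0.122). GDF15, a stress cytokine gene of the p53 list, rose by 1.09 ± 0.058. With wortmannin the same members fell together, except that CEBPB (−0.32) did not pass.

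Of 19 glycolysis genes, 3 rose and 7 fell with Polygalae (4 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.273). Among them ALDOC (2.01 ± 0.153) and ENO2 (0.88 ± 0.049) rose, while PKM (−0.36 ± 0.029), LDHA (−0.30 ± 0.03) and GAPDH (−0.24 ± 0.033) fell. The hypoxia-responsive regulator BHLHE40 rose by 0.49 ± 0.05, while the glucose transporter SLC2A1 of the same hypoxia list fell by 0.14 ± 0.03. Of 24 NRF2 targets, 9 rose and 4 fell (13 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0742). Both ferritin chains were among the risers (FTL by 0.35 ± 0.057 and FTH1 by 0.32 ± 0.057). The interferon-induced IFIT2 was up by 1.13 ± 0.248 with Polygalae.

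A fall of ATOH8 and the ID genes with the dose of Zizyphi may reflect a lower BMP signal, since these genes are known BMP targets. The hypothesis was tested on 11 other measured BMP targets: their mean slope was −0.173 ± 0.033 per 5-fold dose step (9 of 11 negative; two-sided exact permutation p = 0.0036 over 1680 orders of the 9 libraries, and 0.009 adjusted over 5 such tests). No single gene of these passed over all genes and 3 did adjusted over the list alone, and without DLX3, which had the largest slope, the mean was −0.102 (p = 0.0095 in the exact test). For Longan, where ID2, ID3 and ID4 fell, the mean was −0.083 ± 0.03 (exact permutation p = 0.015, 0.025 adjusted), and −0.063 without NOG (exact permutation p = 0.042). With Zizyphi, the most precisely measured members had small slopes: SMAD7 −0.04 ± 0.03, BAMBI −0.06 ± 0.03 and SMAD6 −0.08 ± 0.033. MSX1 and MSX2 were at 0.04 ± 0.065 and 0.03 ± 0.058. Larger falls had larger SE, as for HEY1 (−0.28 ± 0.086), SMAD9 (−0.27 ± 0.095) and DLX3 (−1.14 ± 0.295). With Longan, SMAD6, SMAD7 and BAMBI were at −0.06, −0.04 and −0.06. Both means go in the direction of the hypothesis, on the libraries in which the pattern was found, but a fall across BMP targets in general is not shown.

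GPX1 and SELENOW fell with the dose of both Schisandrae and Aucklandiae, which may reflect a lower level of selenoprotein transcripts as a class. Of 13 other measured selenoprotein genes, 11 had a negative slope with Schisandrae, with a mean of −0.037 ± 0.015 (exact permutation p = 0.038, 0.048 adjusted over the 5 tests), but without SELENOH the mean was −0.026 (exact permutation p = 0.076). The mean lies, by more than 2 SE, above 0.5 times the −0.167 of GPX1 and SELENOW, which argues against a fall of that size in the class mean. A fall of only some members is left open, since a mean cannot show it. GPX1 and SELENOW were also picked because their slopes passed. With Aucklandiae the mean was −0.017 ± 0.014 (exact permutation p = 0.28, 0.28 adjusted), against −0.171 for GPX1 and SELENOW. This argues against a fall of the class mean by that size, with the same limits. SELENOT and SELENOO had been seen before the list was written and were left out. With them the means were −0.035 (exact permutation p = 0.045) and −0.016 (exact permutation p = 0.26). Single genes did go the same way: SELENOH fell with Aucklandiae (slope −0.14 ± 0.025), and DIO2, which was not on the list, fell with Schisandrae (−0.13 ± 0.023) and Aucklandiae (−0.10 ± 0.021). With DIO2 and further selenoprotein genes put back, 19 in all, the means were −0.024 ± 0.014 (exact permutation p = 0.12) and −0.023 ± 0.011 (exact permutation p = 0.062), both still more than 2 SE above 0.5 times the values of GPX1 and SELENOW.

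The rise of lysosome genes with the dose of Polygalae may extend to lysosomal genes outside the fixed list, although the fixed list itself did not pass in the slope when the correlation was estimated (adjusted p = 0.109 with an estimated correlation). In 43 further genes the mean slope was 0.104 ± 0.017 (exact permutation p = 0.0012, the smallest that 1680 orders can give, 0.006 adjusted over the 5 tests), against 0.229 in the fixed list. Of the 43, 16 rose with dose (22 adjusted over the list alone), among them the cathepsin CTSL (0.43 ± 0.046), the cholesterol exporter NPC1 (0.35 ± 0.041) and the ceramidase ASAH1 (0.32 ± 0.039), while 10 had a negative slope. NPC2 and MCOLN3 had been seen before and were left out. With them the mean was 0.122 (exact permutation p = 0.0012).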
